A study of Homo sapiens with 55 samples.

How the data were processed

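Each sample was hybridised to a single-channel Affymetrix array, with 55 arrays in the table and no column from another sample. The deposited values are intensity values on a linear scale, summarised per probe set by MAS5, per the submitters' processing notes, with no version given. From the values, the authors scaled each array globally: the mean after trimming 2% at each end was 500.1 to 500.2 in every array. Detection calls were not used here, scanner files were not analysed here, and other settings of the summarisation are not given in the sources used here. Global scaling assumes that most transcripts do not differ between samples, and MAS5 signals of dim probe sets are noisy.

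Groups were taken from the source label, which separates 9 ETP samples from 46 other T-ALL samples. The titles describe all 55 as atypical, and the source label was followed. Replicate numbers within a group only name a sample. Scan date and batch are not given in the sources used here, so no batch was tested. No arrays held identical values, and Pearson correlations between arrays ran from 0.652 to 0.932.

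Of 22283 probe sets, 68 controls were left out, as were 52 for XIST, TSIX and Y-linked genes. Of the others, 19034 carried 1 gene symbol in the platform annotation, 1022 several and 2107 none in the annotation used, and these last were tested but not named. Symbols were updated through Entrez gene identifiers in a table of assembly GRCh38.p14, where 19022 probe sets matched and 0 symbols changed. No coordinates were used.

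Signals were transformed as log2(signal + 32), so fold changes are on that scale and understate the change of dim genes. Probe sets at or above their array median in at least 9 arrays were tested, 13922 in all. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust settings, two-sided) with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Errors on log2 changes are the fit's standard errors. A gene was represented by its tested probe set with the highest mean signal among those naming only that gene, and for called genes, other probe sets that were not called or ran the other way are given in the text. On simulated data of 9 against 46 arrays and 13922 probe sets, of which 200 changed, 80% of log2 changes of 1 and 97% of log2 changes of 2 were recovered, and 4.32% of calls were unchanged probe sets. With no change simulated, 1 probe set was called. The simulation drew independent normal noise with the T-ALL spread in both groups, so it leaves out correlation between genes and unequal spreads. Among 100 splits of the real arrays into 9 and 46, 16 other than the real one gave calls, at most 91.

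The gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Of 22 lists, 21 had at least 3 tested members and the other was not analysed here. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists. Of these, 11 were called, 5 were called with an estimated correlation (CD1, CD8 and CD5; CD3 and T-cell receptor; thymocyte; stem and progenitor; cytokine and JAK-STAT) and 12 in fry, which asks whether a list's genes move, on balance, in 1 direction. Named genes were the 12 largest rises and 12 largest falls among called genes with at least 8 of 9 ETP arrays on that side of the T-ALL median. All tested members of the 2 phenotype lists and the 4 members with the smallest adjusted p of every other list were named as well. Genes outside this rule are named where a count of 5 or fewer, or an exception, called for it, and were chosen after their values were seen. Array similarity and 3'/5' ratios were compared by permutation tests with 100000 resamples.

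Alternatives covered the filter on low signals, the pseudocount (1 and 128), quantile normalization, scaling to the 75th percentile, plain eBayes, group weights, 3'/5' ratios as covariates, the mean of a gene's probe sets, other set tests and each ETP array left out in turn. The removal of the 3 arrays with a 3'/5' ratio above 3, and that of T-ALL replicate 20, which had the lowest mean correlation with its group (0.740), were chosen after seeing the data.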

Results

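Gene expression was measured on single-channel oligonucleotide arrays in 55 samples of leukaemic cells taken at diagnosis of T-cell acute lymphoblastic leukaemia (T-ALL). The labels place 9 samples in early T-cell precursor leukaemia (ETP), a form whose cells resemble the earliest thymic immigrants, and 46 in T-ALL without that designation. RNA came from frozen mononuclear cells of marrow or blood. The median signal per array ran from 163 to 271, and the number of arrays limits the precision of every value below. The samples are numbered as separate cases, but nothing else in the labels states separate donors, so p-values measure only the spread between these samples.

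The main comparison asked which transcripts separated ETP from the other T-ALL samples. In the 9 ETP samples, genes of the T-cell receptor complex and of thymocyte maturation were lower, and genes of blood stem and progenitor cells were higher. CD1B, a lipid antigen-presenting molecule of cortical thymocytes, was 13.8-fold lower (log2 change -3.79 ± 0.76 SE, adjusted p = 0.00106). The related CD1E was lower by a log2 value of -4.81 ± 1.08 (adjusted p = 0.0043), but its other probe set stood at -2.50 (adjusted p = 0.0483). The CD1E signal in ETP, 23.7, lay below the pseudocount, and its change ran from -3.75 to -5.79 across pseudocounts. The largest rise among the named genes was that of IGFBP7, a secreted growth factor binding protein, at 9.07-fold (log2 change 3.18 ± 0.52 SE, adjusted p = 6.04e-05). Of 13922 probe sets tested with limma, 703 passed an adjusted p of 0.05, 336 of them higher and 367 lower in ETP. At least a 2-fold change was seen for 340 of these, 175 higher and 165 lower, or for 213 at a pseudocount of 128. Counted by gene, 479 of 8373 passed, 228 higher and 251 lower. The 703 called probe sets became 429 when ETP replicate 9 was left out and 450 when ETP replicate 6 was left out. Of the 703, 58.3% stayed called without replicate 9 and 60.6% without replicate 6.

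Among the 12 largest rises were transcription factors, adaptor proteins and products of other blood lineages. MYCN, a MYC family transcription factor, rose by 2.67 ± 0.58 on the log2 scale (SE, adjusted p = 0.00317), with 8 of 9 ETP arrays above the T-ALL median. MEF2C, a transcription factor of lymphoid and myeloid progenitors, rose by 2.60 ± 0.50 in 9 of 9 arrays (adjusted p = 0.000633). IGLL1, part of the surrogate light chain of the pre-B-cell receptor, rose by 2.86 ± 0.77 (adjusted p = 0.0191), from a log2 level of 9.50 ± 2.32 (SD, n = 46) to 12.36 ± 0.95 (SD, n = 9). The tryptases TPSAB1 and TPSB2, proteases of mast cells, each rose by 2.56, but they are near-identical copies whose probe sets can cross-hybridise, so the 2 values are not separate. HPGDS, which makes prostaglandin D2 in mast cells and megakaryocytes, rose by 2.34 ± 0.69 (adjusted p = 0.0337). Its call was lost without ETP replicate 1, 2, 3, 5, 6 or 9, at adjusted p between 0.0569 and 0.085, and without the arrays of high 3'/5' ratio (0.105). The remaining rises were JUP at 2.73, LAT2 at 2.31, STAP1 at 2.29, CCND2 at 2.21 and MLC1 at 2.16. Across pseudocounts JUP ran from 2.09 to 3.19, STAP1 from 1.66 to 2.77 and MLC1 from 1.51 to 2.73. TPSB2 ran from 1.95 to 2.95, so the sizes and ranks of these rises are not fixed. LAT2 (2.11 to 2.40) and CCND2 (2.03 to 2.29) moved less. JUP is a junction protein, LAT2 and STAP1 are adaptors of antigen receptor signalling, and CCND2 is a D-type cyclin. A further LAT2 probe set changed by 0.10 and was not called.

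The 12 largest falls included CD1B and CD1E, and MAL, ELOVL4, DNTT and AQP3 of the thymocyte list. MAL, a membrane raft protein of maturing T cells, fell by 3.49 ± 0.56 (adjusted p = 4.59e-05), and like CD1B it was lower in 9 of 9 ETP arrays. BCL11B, a transcription factor required for T-lineage commitment, fell by 2.30 ± 0.30 (adjusted p = 8.82e-07), from 11.62 ± 0.68 (SD, n = 46) to 9.32 ± 1.49 (SD, n = 9). SIT1, an adaptor of T-cell receptor signalling, fell by 2.67 ± 0.34 (adjusted p = 7.87e-07). ENO2, a glycolytic enolase, fell by 2.46 ± 0.29 and had the smallest adjusted p of the named genes (1.12e-07). BEX3 fell by 3.39, with 8 of 9 ETP arrays below the T-ALL median. ETP replicate 4, at 12.96, lay above the T-ALL mean BEX3 level of 12.22 (log2). AQP3, a water and glycerol channel, fell by 2.25. ELOVL4, a fatty acid elongase, was lower by a log2 value of -2.59, but its ETP signal, 21.5, lay below the pseudocount, and the change ran from -1.63 to -3.80 across pseudocounts, so its size and rank are not fixed. The other probe sets of AQP3 were lower by smaller amounts and were not called. ALDH1A2, which makes retinoic acid, fell by 3.34 ± 0.98 (adjusted p = 0.0325), a call lost without ETP replicate 1, 3, 6, 7 or 9 (adjusted p 0.0537 to 0.0748). DNTT, the template-independent polymerase of receptor gene rearrangement, fell by 2.44 (adjusted p = 0.00948), a call lost without ETP replicate 6 (0.052) or 9 (0.0526). It was below the T-ALL median in 8 of 9 ETP arrays, but ETP replicate 7, at 14.14, exceeded the T-ALL maximum of 13.44 (log2). NOTCH3, a NOTCH receptor, fell by 2.22 (adjusted p = 0.0215), a call lost without ETP replicate 1, 8 or 9 (0.0504 to 0.0701).

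**Figure D1:**
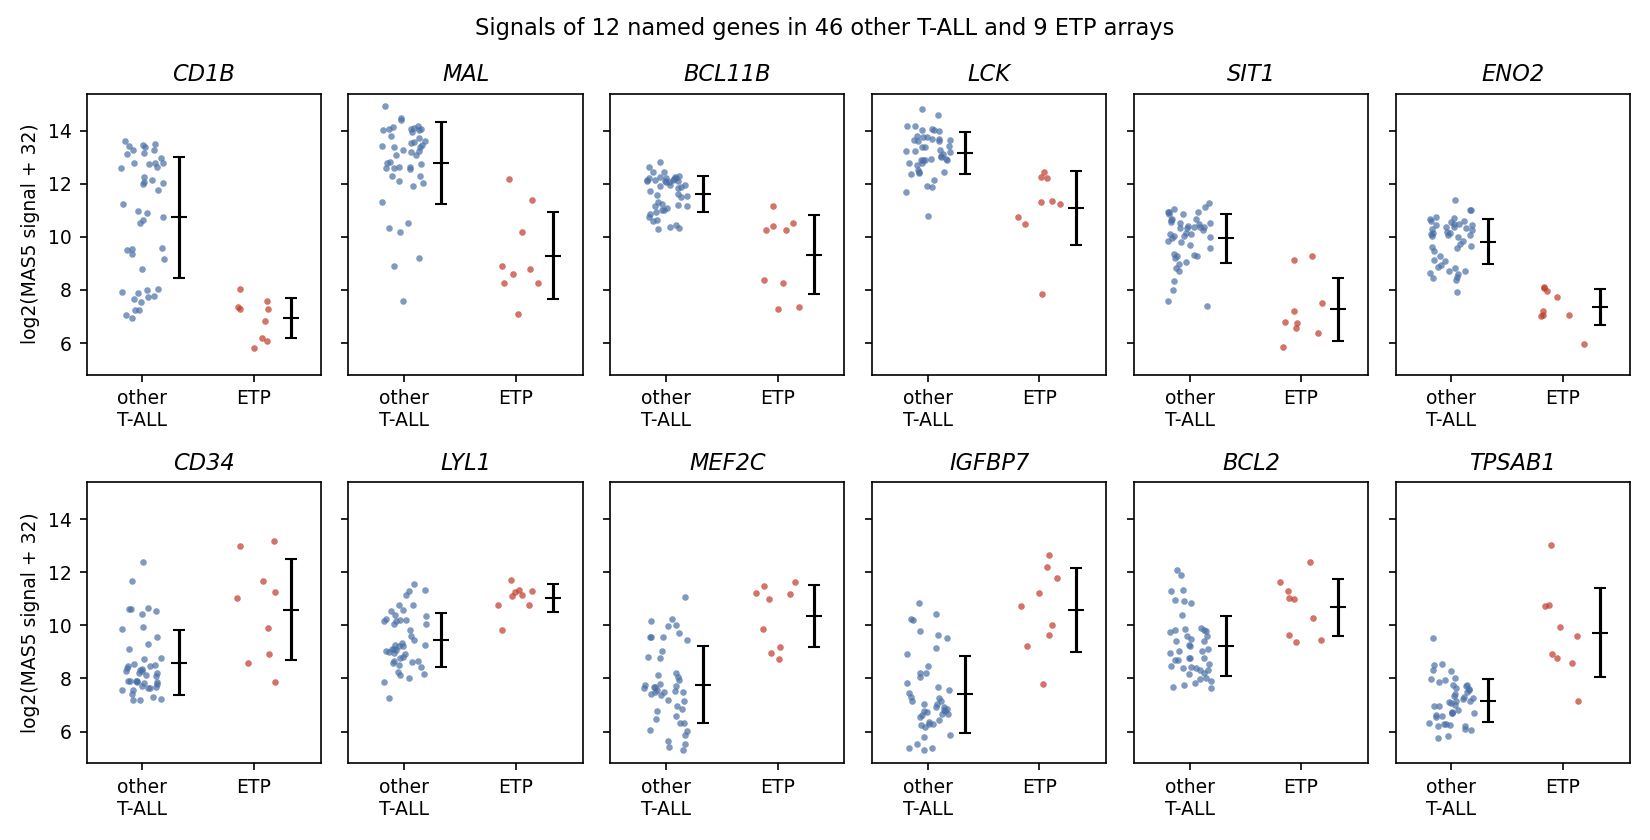
Log2(MAS5 signal + 32) of 12 named genes, with a point per array for 46 other T-ALL samples and 9 ETP samples, and the group mean with its SD drawn beside the points. BCL11B lay at 11.62 in other T-ALL and 9.32 in ETP, while MEF2C was higher in ETP by 2.60.

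ETP leukaemia is usually recognised by weak or absent CD1, CD8 and CD5 protein with stem cell or myeloid antigens. How the 9 samples were assigned is not stated in the labels, so the 2 lists built on this phenotype are not independent evidence of their direction. Of 7 CD1, CD8 and CD5 genes tested, CD1E and CD1B fell and 5 did not pass over all probe sets, against 6 passing when adjusted over the list alone. CD1A was lower by a log2 value of -1.83 ± 0.61 (adjusted p = 0.0658) and CD8A by -1.33 ± 0.48 (adjusted p = 0.0936), both in 9 of 9 ETP arrays. CD1C stood at -1.61, CD5 at -0.61 and CD8B at -0.10, with a further CD8B probe set at -0.90 that was not called. The list fell as a set (camera, adjusted p = 1.68e-05). Among 5 stem cell and myeloid antigens, CD34, the progenitor surface marker, rose by 1.99 ± 0.48 (adjusted p = 0.00829) and 4 did not pass, with 2 passing when adjusted over the list alone. ITGAM stood at 1.32 (adjusted p = 0.0645) and at 0.23 in its other probe set, HLA-DRA at 0.79, KIT at 0.55 and ANPEP at -0.25. With 1 ETP array left out, KIT ran from 0.0847 (without replicate 6) to 0.855 (without 2), HLA-DRA from 0.395 to 1.12 and ANPEP from -0.619 to -0.0598. The set was called (camera, adjusted p = 0.0328), but adjusted p = 0.182 with an estimated correlation. That set call was also lost without ETP replicate 4 (0.063), 5 (0.054) or 6 (0.05).

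Genes of the T-cell receptor complex and its signalling fell together. Of 20 tested, 14 fell and none rose, with 18 passing when adjusted over the list alone (mean log2 change -1.18, camera adjusted p = 2.39e-17). LCK, the kinase that starts receptor signalling, fell by 2.07 ± 0.32 (adjusted p = 3.09e-05), and LAT, an adaptor of that signalling, by 2.05 ± 0.34 (adjusted p = 7.2e-05). CD3E, an invariant receptor chain, fell by 1.06 ± 0.19 (adjusted p = 0.000274), with 8 of 9 ETP arrays below the T-ALL median. TRBC1, a receptor beta constant region, fell by 2.00, although its probe sets can also detect its near-identical copy, and 1 of them, at -1.16, was not called (adjusted p = 0.103). LCP2 at 0.04 and TXK at 0.05 did not move with the rest. Of 13 genes of thymocyte recombination and selection, 5 fell (MAL, ELOVL4, DNTT, AQP3 and ADA) and none rose, with 7 passing when adjusted over the list alone (camera, adjusted p = 2.83e-08). Both lists were also called with an estimated correlation, at 0.00172 and 0.0134.

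Among 11 T-lineage transcription factors, BCL11B and LEF1 fell, ETS2 rose and 8 did not pass, with 6 passing when adjusted over the list alone. LEF1, a partner of beta-catenin, fell by 1.02 (adjusted p = 0.0333), but another of its probe sets stood at 0.28, and the call was lost without ETP replicate 1, 3, 4, 6, 8 or 9 (0.0569 to 0.0845) and with the mean of its probe sets (0.222). ETS2 rose by 0.83 (adjusted p = 0.0444), a call lost without ETP replicate 1, 2, 3, 4, 6, 8 or 9 (0.0516 to 0.152) and under 3 processing alternatives (0.0535 to 0.0935). Its other probe set stood at 0.51 (adjusted p = 0.285). GATA3 stood at -0.88 (adjusted p = 0.0549), or -0.567 without ETP replicate 9. The list was not called (camera, adjusted p = 0.212), with a mean of -0.23 and a median of 0.02. Of 12 NOTCH pathway genes, NOTCH3 fell and 11 did not pass, with 1 passing when adjusted over the list alone. CR2 stood at -2.15, TSPAN7 at -1.07 and SHQ1 at -0.70. That list was called lower (camera, adjusted p = 0.0146), but adjusted p = 0.237 with an estimated correlation, and 0.078 without ETP replicate 7.

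Stem and progenitor genes were higher in ETP. Of 18 tested, 10 rose and none fell, with 13 passing when adjusted over the list alone (mean log2 change 1.38, camera adjusted p = 6.34e-12, adjusted p = 0.00898 with an estimated correlation). CD34, which rose, and KIT, which did not pass, also belong to the phenotype list of stem cell and myeloid antigens. Their direction is therefore not independent evidence. Besides IGFBP7, MEF2C and CD34, the risers included NPR3, a natriuretic peptide receptor, at 2.15 ± 0.41 (adjusted p = 0.000629), and LYL1, a basic helix-loop-helix factor, at 1.57 ± 0.34 (adjusted p = 0.00279). A second NPR3 probe set stood at 0.72 and was not called. Per array, the mean of the T-cell receptor list ran from 8.95 to 10.41 in ETP and from 10.23 to 11.86 in other T-ALL, so that 3 of 46 T-ALL arrays lay within the ETP range. The lowest of these, T-ALL replicate 20, also had the highest HLA class II mean (12.43) and killer cell mean (11.34) of the T-ALL arrays. The others, T-ALL replicates 11 and 17, had stem list means of 9.85 and 9.473. The stem list overlapped more, with 14 of 46 T-ALL arrays at or above the lowest ETP array.

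**Figure D2:**
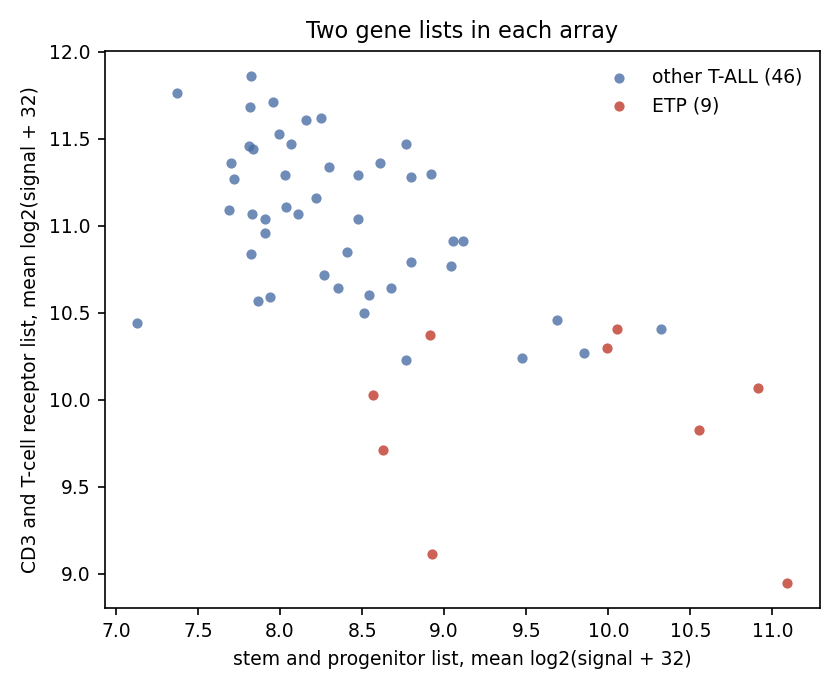
Each point is an array, with the mean log2(signal + 32) of the stem and progenitor list on the horizontal axis and that of the CD3 and T-cell receptor list on the vertical axis, for 9 ETP and 46 other T-ALL samples. The T-cell receptor list reached 10.41 in ETP and started at 10.23 in other T-ALL.

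Few myeloid genes passed, and the myeloid lists were not tested against the lists above. Of 22 granulocyte and monocyte differentiation genes, SPI1 and CSF2RB rose and 20 did not pass, with 6 passing when adjusted over the list alone. SPI1, the master transcription factor of myeloid cells, rose by 1.33 ± 0.38 (adjusted p = 0.027), a call lost without ETP replicate 4, 6, 8 or 9 (0.0603 to 0.085). CSF2RB, the shared beta chain of myeloid cytokine receptors, rose by 1.11 ± 0.33 (adjusted p = 0.0387), a call lost without ETP replicate 4, 6, 8 or 9 (0.0781 to 0.108), without a filter on low signals (0.051) and without the arrays of high 3'/5' ratio (0.0532). GFI1 stood at -1.54 (adjusted p = 0.0524). The list was not called (camera, adjusted p = 0.0573), although it was at 0.0074 without ETP replicate 1, 0.0097 without 2, 0.033 without 7 and 0.0075 without 9, and at 0.02 without T-ALL replicate 20. Its mean of 0.31 was 0.0231 without ETP replicate 8 (adjusted p = 0.64) and 0.144 without 4 (0.33). None of 14 mature monocyte and neutrophil markers passed (mean 0.07, camera adjusted p = 0.768), with 0 passing when adjusted over the list alone. Without ETP replicate 4 that mean was -0.22 and without ETP replicate 8 it was -0.38. Those 2 arrays had the highest ETP means of this list, 11.43 and 12.66 against 7.096 to 9.848 in the other 7, and also the highest SPI1 levels, 9.799 and 9.772. The third highest SPI1 level, 9.494, was in ETP replicate 9, with a mean of this list of 7.961. CD14 stood at 0.41, FCGR3B at 0.43, S100A12 at 0.40 and CD163 at 0.21, but with 1 ETP array left out they reached as low as 0.00377, -0.0618, -0.0799 and 0.0314.

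Of 19 cytokine receptor and JAK-STAT genes, CISH, PIM1 and CSF2RB rose and 16 did not pass, with 9 passing when adjusted over the list alone. CISH, a feedback inhibitor induced by STAT5, rose by 1.21 ± 0.32 (adjusted p = 0.0163, or 0.0515 without ETP replicate 3). PIM1, a survival kinase induced by cytokines, rose by 1.07 ± 0.29 (adjusted p = 0.0201), a call lost without ETP replicate 3, 6 or 8 (0.0518 to 0.0632) and without the arrays of high 3'/5' ratio (0.0554). PIM2 stood at 0.70. The list was called (camera, adjusted p = 0.000218), also with an estimated correlation (adjusted p = 0.0434). Among 9 T-ALL oncogenes MEF2C, LYL1 and SPI1 rose and BCL11B fell, with 5 passing when adjusted over the list alone, and the list was not called (adjusted p = 0.0989). In the BCL2 family of 11 genes BCL2 and BCL2L2 rose, with 2 passing when adjusted over the list alone, and the list was not called (adjusted p = 0.121). BCL2, an inhibitor of apoptosis, rose by 1.45 ± 0.40 (adjusted p = 0.0215), a call lost without ETP replicate 1, 6 or 9 (0.0515 to 0.073) and without the arrays of high 3'/5' ratio (0.0532), and its other probe set stood at -0.02. BCL2L2 rose by 0.99, while BAX stood at 0.26 and BIK at 0.34 (0.115 without ETP replicate 8 and -0.0661 without 6).

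Of 26 cell cycle genes tested, 5 fell, 21 did not pass and none rose (falls in TTK, RRM2, CCNA2, CCNB2 and FOXM1), with 16 passing when adjusted over the list alone. The list was called (mean log2 change -0.65, camera adjusted p = 1.29e-10), but adjusted p = 0.183 with an estimated correlation. TTK, a spindle checkpoint kinase, fell by 1.13 (adjusted p = 0.0135, or 0.0898 without ETP replicate 9). RRM2, a subunit of ribonucleotide reductase, fell by 1.15 (adjusted p = 0.0313), a call lost without ETP replicate 3, 6 or 9 (0.0632 to 0.122) and without the arrays of high 3'/5' ratio (0.0584). The cyclins CCNA2 and CCNB2 each fell by 0.87. The CCNA2 call was lost without ETP replicate 2, 3, 5, 6 or 9 (0.0546 to 0.115) and without those arrays (0.0843), and that of CCNB2 without ETP replicate 2, 3, 4, 6, 8 or 9 (0.0505 to 0.17) and under 4 processing alternatives (0.0527 to 0.0588).

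Markers of other cell types that marrow or blood can hold were measured beside these groups. Over all lists, 29 of 48 named genes that did not pass moved by more than 1.5 times when 1 ETP array was left out, against 1 of 46 called genes, BLNK. The move is relative to a gene's own change, so small changes pass 1.5 times easily. Called genes were selected for large changes, so the counts do not compare stability. Of 8 B cell markers, BLNK, a B-cell adaptor, rose by 1.15 ± 0.36 (adjusted p = 0.0487), with 3 passing when adjusted over the list alone. Its call was lost without ETP replicate 2, 3, 5, 7, 8 or 9 (0.0533 to 0.252) and under 7 processing alternatives (0.0527 to 0.0972). Without ETP replicate 7 its change was 0.635. PAX5 stood at 0.96, CD79B at 0.85 and CD22 at 0.44, or at 0.54, 0.53 and 0.14 without ETP replicate 7. The list was called (camera, adjusted p = 0.00525), but adjusted p = 0.222 with an estimated correlation, and 0.18 without ETP replicate 7. Of 5 megakaryocyte and platelet markers, ITGA2B, the platelet integrin alpha chain, rose by 0.81 ± 0.19 (adjusted p = 0.00639), with 3 passing when adjusted over the list alone, while PPBP stood at 1.52, PF4 at 1.02 and CLEC1B at 0.48. That list was called (adjusted p = 0.00525), but adjusted p = 0.143 with an estimated correlation. None of 10 HLA class II presentation genes passed, with 0 when adjusted over the list alone (CD74 at 1.29, HLA-DMA at 0.82, HLA-DQB1 at 0.64 and HLA-DMB at 0.45). The class II list was called higher (adjusted p = 0.0146), but adjusted p = 0.444 with an estimated correlation, and 0.06, 0.071 or 0.19 without ETP replicate 3, 5 or 7. Without replicate 7 HLA-DQB1 was 0.402 and HLA-DMB 0.301.

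Of 13 natural killer and cytotoxic T markers, PRF1, the pore-forming protein of cytotoxic granules, rose by 1.13 (adjusted p = 0.0403), with 1 passing when adjusted over the list alone, and NKG7 at 0.66, GNLY at 0.58 and KLRD1 at 0.35 did not pass. The PRF1 call was lost without ETP replicate 1, 2, 3, 4, 6 or 7 (0.0615 to 0.134), without a filter (0.0547) and without the arrays of high 3'/5' ratio (0.079). The killer cell list was not called (adjusted p = 0.0592), although it was at 0.035, 0.01, 0.038 and 0.0037 without ETP replicate 1, 2, 6 and 9, and at 0.022 without T-ALL replicate 20. Without ETP replicate 3 it was at 0.61, with a mean of 0.125 against 0.378. GNLY was 0.187 without ETP replicate 4, and NKG7 was 0.389 and KLRD1 0.119 without 3. None of 9 erythroid markers passed (ALAS2 at 0.86, EPB42 at 0.81, KLF1 at 0.53 and AHSP at 0.50; list adjusted p = 0.212, or 0.013 without ETP replicate 2 and 0.88 without 3). Without ETP replicate 3 these genes stood at 0.306, 0.316, 0.270 and 0.0685. None of 5 dendritic cell markers passed (CD1C at -1.61, LAMP3 at -0.98, IRF7 at 0.56 and FCER1A at 0.16). That list was not called (camera, adjusted p = 0.614), with a mean of -0.37 and a median of 0.03. Without ETP replicate 5 the mean was -0.614, LAMP3 -1.56 and FCER1A -0.226. CD1C also belongs to the CD1, CD8 and CD5 list, and without CD1C the dendritic mean was -0.0585. Adjusted over the list alone, 0 erythroid markers and 1 dendritic marker, CD1C, passed. Neither 12 immediate early and heat shock genes (IER2 at 0.37, HSPH1 at -0.48, ATF3 at -0.38 and DNAJB1 at -0.27; adjusted p = 0.833) nor 15 interferon response genes (IFI27 at 0.81, XAF1 at 0.62 and OAS1 at 0.60; adjusted p = 0.605) had a member that passed, and 0 passed when adjusted over either list alone. IFI27 was 0.320 without ETP replicate 4, XAF1 0.388 without 6, HSPH1 -0.224 without 9 and ATF3 -0.240 without 3.

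**Figure D3:**
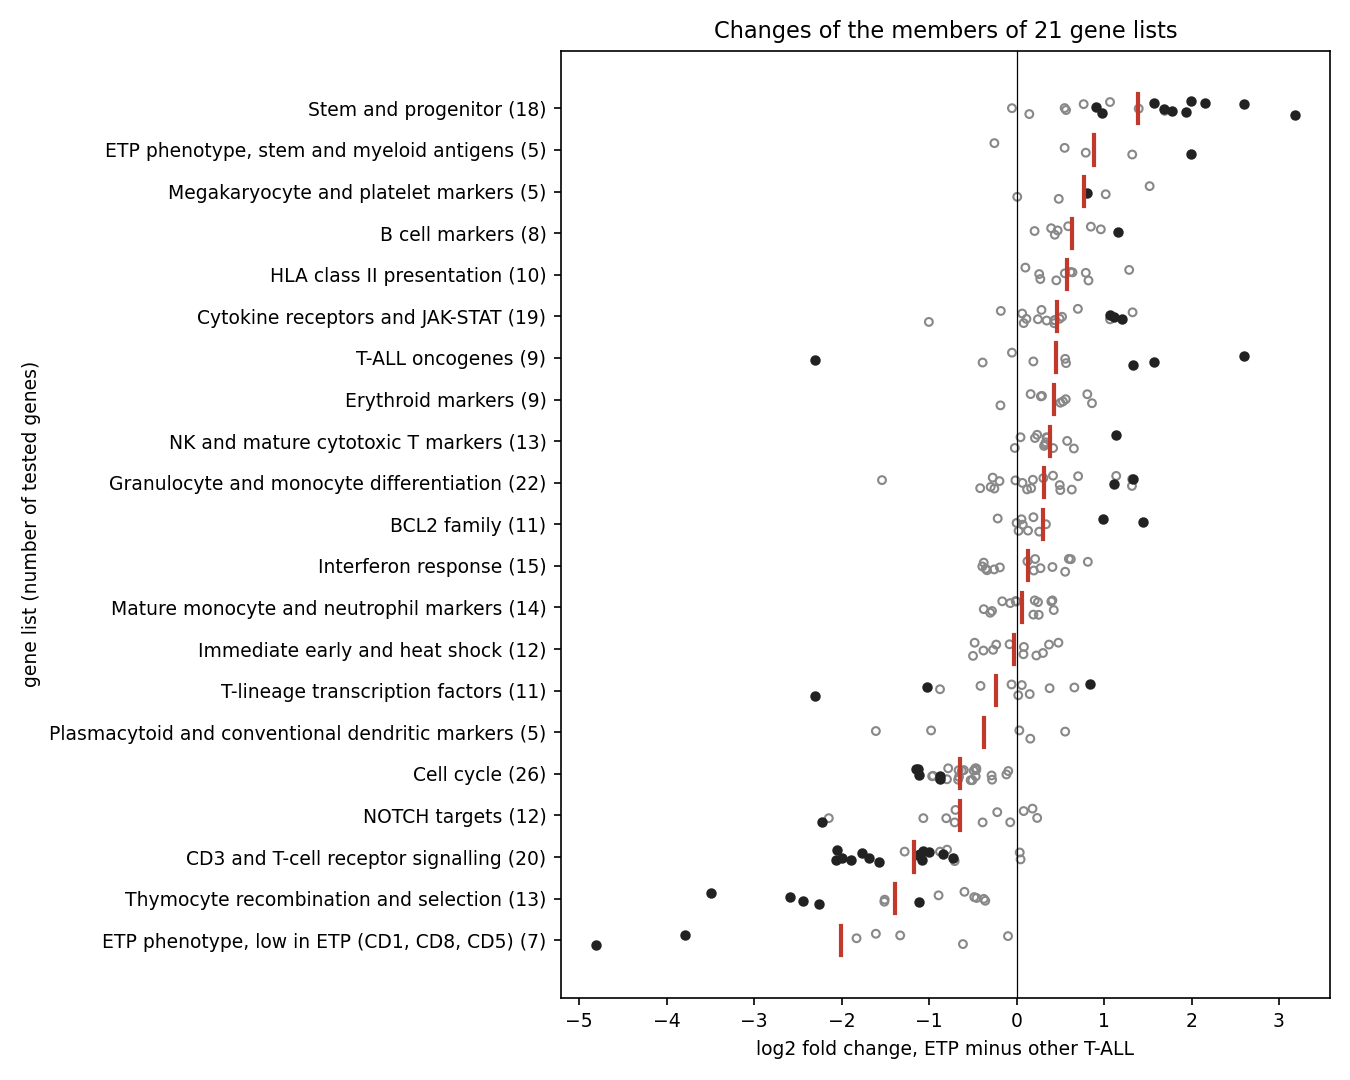
Log2 change (ETP minus other T-ALL) of the tested members of 21 gene lists, with a filled point for a gene past an adjusted p of 0.05, an open point for one that was not, and a red bar at the list mean. The T-cell receptor list had a mean of -1.18 and the stem and progenitor list a mean of 1.38.

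Whether ETP arrays resembled each other more than arrays drawn at random was asked separately. Their mean pairwise Pearson correlation across probe sets was 0.810, against 0.823 ± 0.013 (SD) for random sets of 9 arrays, and the difference was not detectable (two-sided permutation p = 0.307, adjusted p = 0.53 over 3 tests). Random sets were drawn mostly from T-ALL arrays, whose own mean was 0.833. Between ETP and T-ALL arrays the mean was 0.799, below that among ETP arrays, a difference that was not tested. RNA quality, read from 3'/5' signal ratios of control probe sets, did not differ detectably between the groups. The log2 GAPDH ratio differed by -0.07 (permutation p = 0.622, adjusted p = 0.622) and the log2 ACTB ratio by -0.17 (permutation p = 0.353, adjusted p = 0.53). A ratio above 3 was found in 3 arrays, 1 ETP and 2 other T-ALL.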

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

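The test on SPI1 and CSF2RB, the test of a uniform factor on T-cell receptor genes and the repeats of the share test without CD1C and under other settings were chosen only after the results were seen. The 703 called probe sets were set against chance and RNA quality. Of 100 splits of the 55 arrays into 9 and 46, 1 gave as many calls, which was the real one, and the highest other split gave 91. Chance is thus an unlikely source of that count, although 100 splits cannot exclude it. How the 9 samples were assigned is not stated, so the count does not say what sets them apart. With both 3'/5' ratios as covariates 91.2% of the called probe sets remained called, and 75.1% did without the 3 arrays with a ratio above 3. The ratios did not differ detectably between the groups, so the covariates could change little. As measured by these ratios RNA quality did not account for most calls, but 2 control ratios cover RNA quality only in part. The array batch stays open and untested, as does the biological difference that the labels name.

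The lower T-lineage genes in ETP could reflect a lower share of T-lineage cells. The prediction set beforehand was that such a share would raise the markers of other cell types together. The B cell list, at a mean of 0.633, and the dendritic list, at -0.369, lay 2.41 standard errors apart, beyond the bound of 2 set beforehand. A lower share need not raise every other cell type alike, so this difference cannot decide the question. The standard errors are over the genes of a list and leave out the spread between arrays. With 1 ETP array left out the largest difference between any 2 of the lists ran from 2.31 to 3.99, but the pair that gave it changed. It was B cell against erythroid without ETP replicate 3, 4 or 8. Without ETP replicate 5 the dendritic mean was -0.614, and without ETP replicate 7 the B cell mean was 0.306. Without a filter on low signals the dendritic mean was -0.0294. The stricter filter gave 1.35, the only 1 of 21 alternatives at or below 2. The difference of 2.41 was the largest of 10 pairs of lists, and CD1C, a dendritic marker, also belongs to the phenotype list. Without CD1C the largest difference was 2.00 standard errors, at the bound, and the dendritic mean was -0.0585. Of 20 T-cell receptor genes, 5 changed by an amount that differed from the list mean of -1.18. TRBC1, LCK and LAT fell by more, and LCP2 and TXK did not pass the test for a fall. This count lay exactly at the bound, which was set after the results were seen. A further TRBC1 probe set, at -1.16, lay near the list mean, so the test does not decide against a uniform loss. A smaller T-lineage share, alone or combined with lower expression within the leukaemic cells, stays open as a hypothesis.

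Of 22 granulocyte and monocyte differentiation genes only SPI1 and CSF2RB rose, the list was not called (adjusted p = 0.0573), and these 2 rises might come from admixed mature monocytes and neutrophils. The differentiation list exceeded the mature markers by a mean log2 value of 0.245 with a standard error of 0.166, which leaves the list as a whole undecided. The rise of SPI1 and CSF2RB exceeded that of the mature markers in the same arrays by 1.16 (95% confidence interval 0.303 to 2.01, permutation p = 0.00849), but these 2 were picked as the only called members of the list, so this decides nothing. The mature markers themselves differed by 0.0656 (95% interval -1.04 to 1.17), too wide to exclude a change in their share, and the admixture stays open. ETP replicates 4 and 8 had the highest ETP means of the mature list (11.43 and 12.66) and the highest SPI1 levels (9.799 and 9.772), while ETP replicate 9 had the third highest SPI1 level (9.494) at a mature list mean of 7.961.

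Of 119 sets of 9 ETP values, 18 held an array far from the rest. For a single set, chance gives about 1 in 20 if its values are independent and normal. The sets share the same 9 arrays, and flagged genes such as BLNK and LAMP3 count again in their flagged lists. The 18 are therefore not separate, and whether they exceed chance was not tested. The value given is the gap to the nearest array as a share of the range. ETP replicate 7 was highest for BLNK (0.558), PAX5 (0.616), CD22 (0.634), HLA-DMA (0.512) and the B cell list (0.545). In that array 6 of the 8 tested B cell markers exceeded every T-ALL array, among them MS4A1 at 13.46 against a T-ALL maximum of 11.55 (log2). ETP replicate 5 was highest for LAMP3 (0.711) and the dendritic list (0.596). ETP replicate 6 was highest for ELOVL4 (0.65) and XAF1 (0.612) and lowest for CD8A (0.65). ETP replicate 9 was lowest for LCK (0.567), HSPH1 (0.539) and OAS1 (0.54). ETP replicate 2 was lowest for ENO2 (0.495) and PF4 (0.555) and highest for the GAPDH 3'/5' ratio (0.521). ETP replicate 3 was highest for KLRD1 (0.541), and ETP replicate 4 for the immediate early and heat shock list (0.578).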

How the results depend on the processing

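The removals of the 3 arrays with a 3'/5' ratio above 3 and of T-ALL replicate 20 were chosen after seeing the data. No paired analysis was possible because the case numbers in the titles are unique and the groups share none. The repeats of the T-lineage share test were too. Of 46 called named genes, 29 stayed called under every alternative that tested them and 0 reversed, but the stricter filter removed 9 of the 29 from the test. The cause of the changes below was not tested. Calls numbered 638 without a filter, 650 with the stricter filter, 656 and 730 at pseudocounts of 1 and 128, 767 after quantile normalization, 749 after scaling to the 75th percentile, 691 with plain eBayes, 610 with group weights, 716 with ratio covariates and 615 without the arrays above 3, against 703. The share lower in ETP was 59.0% after 75th percentile scaling, 58.3% after quantile normalization and 46.4% without a filter, against 52.2%. Between pseudocounts, 11 of the 46 called changes differed by more than 1.5 times. At a pseudocount of 128, 213 probe sets passed with a 2-fold change, against 340.

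Adjusted p-values of lists moved as follows. Reversals of a list are those of camera's direction. Without a filter the dendritic list reversed (0.62). With the stricter filter the B cell list lost its call (0.051) and the immediate early list reversed (0.93). At a pseudocount of 1 the stem cell and myeloid antigens lost theirs (0.053). The granulocyte and monocyte list was called at a pseudocount of 128, after quantile normalization and after 75th percentile scaling (0.031 each), and without the arrays above 3 (0.013). The killer cell list was called after 75th percentile scaling (0.037) and without those arrays (0.013), as was the erythroid list without them (0.013). Quantile normalization reversed the immediate early list (0.94), and ratio covariates reversed the mature myeloid list (0.96). With an estimated correlation, calls were lost for the stem cell and myeloid antigens (0.18), HLA class II (0.44), NOTCH (0.24), cell cycle (0.18), B cell (0.22) and megakaryocyte (0.14) lists. In fry HLA class II lost its call (0.16), and the T-ALL oncogenes (0.0049) and the BCL2 family (0.024) gained it.

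Leaving out each ETP array in turn, or T-ALL replicate 20, gave 429 to 869 calls, 204 to 400 higher and 223 to 469 lower. Calls numbered 429 without ETP replicate 9, 450 without ETP replicate 6 and 869 without T-ALL replicate 20, where all 703 calls remained. List adjusted p-values ran from 0.01 to 0.063 for the stem cell and myeloid antigens, 0.0074 to 0.64 for granulocyte and monocyte, 0.25 to 0.97 for mature myeloid, 0.002 to 0.19 for HLA class II, 0.0059 to 0.078 for NOTCH, 0.00075 to 0.18 for B cell, 0.0037 to 0.61 for killer cell, 0.013 to 0.88 for erythroid, 0.46 to 0.99 for immediate early and 0.32 to 0.88 for interferon genes. The B cell list was at 0.18 without ETP replicate 7. Lists reversed without ETP replicate 4 (mature myeloid, mean -0.222, and interferon, -0.00599), 8 (mature myeloid, -0.376), 1 (immediate early, 0.0405) and 9 (immediate early, 0.0294). Uncalled genes that changed sign were CD8B (-0.215 to 0.0798), FCER1A (-0.226 to 0.486), FCGR3B (-0.0618 to 0.606), S100A12 (-0.0799 to 0.699) and BIK (-0.0661 to 0.546). Without the arrays above 3, CD8B was 0.0971 and FCER1A -0.171, and FCER1A was -0.120 at a pseudocount of 1. Gene calls were also lost to processing. Without a filter these were ETS2 (0.0582), CSF2RB (0.051), CCNB2 (0.0571), BLNK (0.0627) and PRF1 (0.0547). With group weights they were ETS2 (0.0535), CCNB2 (0.0527) and BLNK (0.0566), and with ratio covariates CCNB2 (0.0588) and BLNK (0.0685). BLNK was lost at a pseudocount of 1 (0.0602), after quantile normalization (0.0564) and after 75th percentile scaling (0.0527). With the mean of a gene's probe sets LEF1 (0.222) and ETS2 (0.0935) were lost. Without the arrays above 3, HPGDS (0.105), CSF2RB (0.0532), PIM1 (0.0554), BCL2 (0.0532), RRM2 (0.0584), CCNA2 (0.0843), CCNB2 (0.0548), BLNK (0.0972) and PRF1 (0.079) were lost. Signal over background limits dim probe sets, for which no detection call was used.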

Other observations

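The genes in this part were chosen after their values were seen. They form no tested group, and the B cell list fixed beforehand had 1 of 8 members called, with adjusted p = 0.222 with an estimated correlation and 0.18 without ETP replicate 7. VPREB1, the partner of IGLL1 in the surrogate light chain, rose by 2.10 ± 0.60 (limma, adjusted p = 0.0264), and BTK, a kinase downstream of the B-cell receptor, by 2.00 ± 0.36 (adjusted p = 0.000274), each in 9 of 9 ETP arrays. ETP replicate 7 had a VPREB1 level of 13.15 against a T-ALL maximum of 11.72 (log2). The VPREB1 call was lost without ETP replicate 1 (0.0501), 3 (0.058), 5 (0.055), 7 (0.0832) or 9 (0.0533). LYN, a SRC family kinase of B and myeloid cells, rose by 1.51 ± 0.36 (adjusted p = 0.00686), as did each of its 3 probe sets. CD79A at 0.40, MS4A1 at 0.59 and IGHM at 0.47 did not pass, and stood at 0.235, 0.122 and 0.0732 without ETP replicate 7.

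All 3 TPSAB1 probe sets rose. CPA3, a mast cell protease, stood at 1.29 (adjusted p = 0.0687), higher than the T-ALL median in 9 of 9 ETP arrays, and was called with 3'/5' ratios as covariates (0.0372) and without ETP replicate 7 (0.0494). HDC, which makes histamine, stood at 0.71 (adjusted p = 0.246), or 0.357 without ETP replicate 3. KIT at 0.55 (0.0847 without ETP replicate 6) and FCER1A at 0.16 (-0.226 without 5) did not pass. CD44, an adhesion receptor, rose by 1.19 ± 0.34 (adjusted p = 0.0289), with 6 of its 7 probe sets called higher. Its call was lost without ETP replicate 1 (0.0621), 3 (0.0914), 6 (0.0827) or 9 (0.0928). FAT1, an atypical cadherin, fell by 2.17 ± 0.53 (adjusted p = 0.00909), and RASGRP1, an exchange factor of T-cell receptor signalling, by 1.94 ± 0.45 (adjusted p = 0.00548).

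On the gene list means, 3 of 46 T-ALL arrays were at or below the highest ETP array for the T-cell receptor list, and all 3 were at or above the lowest ETP array for the stem list. The lowest of them on the T-cell receptor list, T-ALL replicate 20 at 10.23, stood apart in other ways. It had the lowest mean correlation with the other T-ALL arrays (0.740), a CD14 level of 13.40 and a mature myeloid list mean of 12.23. Its HLA class II mean of 12.43 and killer cell mean of 11.34 were the highest among T-ALL arrays. The others, T-ALL replicates 11 (10.27) and 17 (10.24), had stem list means of 9.85 and 9.473. Their CD1, CD8 and CD5 list means, 7.802 and 7.642, lay within the ETP range of 6.939 to 8.384, as did those of 11 T-ALL arrays in all. For the stem list 1 T-ALL array reached the ETP median, and for the T-cell receptor list 0 did.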
